A study of Oncorhynchus mykiss with 35 samples.

How the data were processed

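The series measured testis RNA of 35 male rainbow trout (Oncorhynchus mykiss), 1 array per fish. Total testis RNA (5 µg) was copied into cDNA with an oligo(dT) primer and a 33P-labelled nucleotide, and the cDNA was hybridized to an array of trout cDNA clones, per the labels' protocols. The deposited values are on a log scale and were taken as log2 expression values, since the base is not given in the sources used here. A different base would rescale every difference printed below and leave the p-values unchanged. Results that use a fixed size, the fold of at least 1.5 and the cut-off of 1 log2 unit for liver RNA, would change with it. The scanner, the background correction and the normalization tool are not given in the sources used here either. A higher value was read as more hybridized RNA.

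The table held 9216 features, of which 192 had no value on any array. These 192 were controls named water (64) or cvu03687 (128), and they were left out. The other 9024 clones had a value on every array and were all tested, with no filter on dim clones. Values ran from 3.74 to 13.2. The sorted values were identical in all 35 columns, with a median of 6.70 and quartiles of 5.97 and 7.53 in each, so the authors had quantile-normalized the arrays before they deposited them. That normalization was kept. It sets the overall signal of each array equal, so a change of total RNA per testis cannot be seen, and every difference is relative to the other clones. Arrays give no read depth, and the number of arrays per group limits the precision.

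Clones were named through the annotation given for this array. A single gene was given for 677 clones (7.50% of those tested), several for 1 clone, and none is named here for 8346. The 677 clones covered 591 genes, and 584 of their gene identifiers were found in the trout gene table (assembly USDA_OmykA_1.1), which was used for names only. A locus identifier in place of a symbol was carried by 125 genes, and 39 further genes with such an identifier were called by their listed synonym. Statements about unnamed clones give the clone identifier alone.

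The groups were 14 untreated fish, 5 with testosterone 0.1 mg for 7 days, 4 with testosterone 0.2 mg for 7 days, 5 with testosterone 0.2 mg for 14 days, and 7 with 11-ketotestosterone 0.25 mg. The titles give 14 days for the 11-ketotestosterone fish, while the sample characteristics and the series text give 7 days, so their duration is uncertain. The untreated fish carry no duration. No batch, date or family is named in the labels.

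Each clone was tested with limma 3.58.1 (lmFit and eBayes, two-sided) in R 4.3.3. All 35 arrays were fitted together in 5 groups that shared 1 estimate of the spread. Contrasts compared each treated group with the untreated fish, the mean of the 3 testosterone groups with the untreated fish, the 2 doses at 7 days, the 2 durations at 0.2 mg, and 11-ketotestosterone with either group of the 0.2 mg testosterone dose. A moderated F test covered all 5 groups. P-values were adjusted by the Benjamini-Hochberg method over the 9024 clones within each comparison, and 0.05 was the threshold. These p-values measure the spread between fish. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.

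Named genes were taken by a rule: for each comparison with untreated fish, up to 12 genes with the largest rise and 12 with the largest fall past the threshold, and up to 6 each way for comparisons between treatments. The rule added all measured genes of the steroidogenesis and the receptor lists, 2 to 4 genes of other lists by smallest p, and at most 2 unnamed clones that rose and 2 that fell. The clone with the smallest p stood for a gene with several.

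The 21 gene lists covered steroidogenesis (8 genes measured), steroid and gonadotropin receptors with the sex hormone-binding globulins shbg and shbgb (6), markers of Leydig cells (6) and Sertoli cells (5), IGF, TGF-beta and other growth factors (5), liver and plasma proteins (12), ribosomal proteins (6) and oxidative phosphorylation (5). These 8 lists had at least 5 genes and were tested with camera (preset correlation 0.01) in 8 comparisons, on the mean over a gene's clones, with adjustment over all 64 tests. The other lists had fewer genes and were only counted: spermatogonia and early germ cell markers (4), meiosis (2), spermiogenesis and axoneme (2), extracellular matrix (4), leukocyte and macrophage markers (2), erythrocyte markers (3), oocyte markers (1), cholesterol synthesis and uptake (1), chaperones and ER stress (4), the retinoid pathway (2) and the proteasome (3). No gene was measured for cell cycle and DNA replication or for smooth muscle and peritubular myoid markers. List members were called over the 591 genes and also adjusted over the list alone. The camera test was repeated with an estimated correlation and beside fry, which tests whether the genes of a set move on balance 1 way.

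The fit was tested on simulated data made from the real means and spreads, with 200 of 9024 clones changed. For testosterone 0.2 mg for 7 days, 52.2% of changes of 0.5 log2 units, 95.5% of changes of 1 and 97.0% of changes of 1.5 were recovered, and 5.78% of the calls were false. For 11-ketotestosterone the shares were 77.6%, 100% and 98.5%, with 5.15% false. On unchanged simulated data 0 of 64 list tests passed, and a steroidogenesis list lowered by 0.5 in the 0.2 mg 7-day group passed in 20 of 20 draws. Means and spreads hold no correlation between genes, so this does not test the preset correlation. That correlation was estimated in the real data at 0.347 for the Leydig and 0.192 for the steroidogenesis list. In other splits of the real fish up to 11 list tests passed (median 0).

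The design, the lists, the rule for named genes and most alternatives were chosen before the data were examined. These alternatives were a second normalization, median centring, leaving out the dimmest 25% of clones, only the arrays compared, array weights, eBayes with trend and robust, the replicate number as a block, genes in place of clones, a fold change of at least 1.5 besides the threshold, and leaving out each array in turn. Replicate numbers 8 to 14 occur only among untreated fish. The block fits these fish exactly, so they add nothing to that fit and its precision is lower. 3 alternatives were chosen after seeing the data: leaving out 4 arrays whose median correlation with the others was under 0.93, adding the mean globin signal of 8 globin clones as a covariate, and matching list members through the array's own spellings. The same 14 untreated fish serve 4 comparisons, so correlations between their changes are given beside 100 simulated unchanged groups. Overlaps of calls are given beside the numbers for independent lists. Equal changes of the 6 Leydig cell genes were tested, after the data were seen, with Hotelling's T-squared on the differences between these genes within each fish, with 1 covariance matrix for the 5 groups and BH over the 4 treated groups. All 35 columns of the table were used.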

Results

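Gene expression was measured in the testes of 35 immature male trout, 13 months old, whose only germ cells were spermatogonia. Of these fish, 14 were untreated and 21 carried an androgen implant. The labels name no group with an implant without hormone. Testosterone was given at 0.1 mg for 7 days (n = 5), at 0.2 mg for 7 days (n = 4) and at 0.2 mg for 14 days (n = 5). The other androgen, 11-ketotestosterone (0.25 mg, n = 7), is testosterone with an added oxo group at carbon 11 and is the main androgen of many male fish. It was given for 7 or 14 days, on which the labels differ. Signals are in log2 units. Differences between groups are given with their standard error, and group levels with the SD between fish. The median SD within groups was 0.229 log2 units. The median correlation of an array with the other 34 ran from 0.904 to 0.968, and 4 arrays lay under 0.93. These were untreated fish 5 (0.916), fish 1 (0.904) and 4 (0.924) of testosterone 0.1 mg, and fish 1 of testosterone 0.2 mg for 7 days (0.924).

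The series asked which genes of the fish testis respond to androgens. In the testis 3 genes of steroid synthesis fell and 5 genes with a symbol other than a locus number rose with each of the 4 treatments. The weakest of these calls were jun with testosterone 0.1 mg (adjusted p = 0.0469) and star with 11-ketotestosterone for 7 or 14 days (adjusted p = 0.0438), and both were lost without single fish, with only the arrays compared and with the globin signal as a covariate. Those that fell were cyp17a1, hsd3b1 and star. The first is the hydroxylase and lyase that makes androgen precursors, the second makes progesterone from pregnenolone, and star carries cholesterol into mitochondria. In untreated fish (n = 14) cyp17a1 stood at 9.53 ± 0.33 and with testosterone 0.1 mg (n = 5) at 8.34 ± 0.52. It stood at 7.69 ± 0.17 (0.2 mg for 7 days, n = 4), 7.89 ± 0.23 (0.2 mg for 14 days, n = 5) and 8.09 ± 0.30 (11-ketotestosterone, n = 7). Each of the 21 treated fish lay below the lowest untreated fish for cyp17a1. Those that rose were il13ra2b, slc39a1, jun, cahz and dmrt1. Of these il13ra2b is an interleukin receptor, slc39a1 a zinc importer and jun a subunit of the AP-1 transcription factor. The gene cahz encodes a carbonic anhydrase and dmrt1 a transcription factor of male gonad development. The signal of il13ra2b went from 7.07 ± 1.14 in untreated fish to 10.06 ± 0.25 with testosterone 0.2 mg for 7 days. Among untreated fish it ran from 5.60 to 8.99. In the mean of the 3 testosterone groups, 845 of 9024 clones changed, 491 up and 354 down. This count was 379 with the mean globin signal as a covariate and 243 with the replicate number as a block. That block fits untreated fish 8 to 14 exactly, which takes them out of the comparison and lowers its precision. Globin signal lay above that of the untreated fish in all 3 groups, by 0.403, 0.915 and 0.276 log2 units. In this mean hsd3b1 was at -1.61 ± 0.13 (adjusted p = 5.19e-12) and il13ra2b at 2.68 ± 0.28 (adjusted p = 2.04e-09). Of the 6 Leydig cell genes 4 fell in it (5 adjusted over the list alone; camera adjusted p = 3.48e-07, and adjusted p = 0.0360 with an estimated correlation). The same 4 of 8 steroidogenesis genes fell (5 adjusted over the list alone; camera adjusted p = 1.23e-05, and adjusted p = 0.0385 with an estimated correlation). Without the 4 arrays under 0.93 both lists had an adjusted p of 0.0921 with an estimated correlation. The F test over the 5 groups called 1073 clones, which covered 87 genes with a name other than a locus number.

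**Figure D1:**
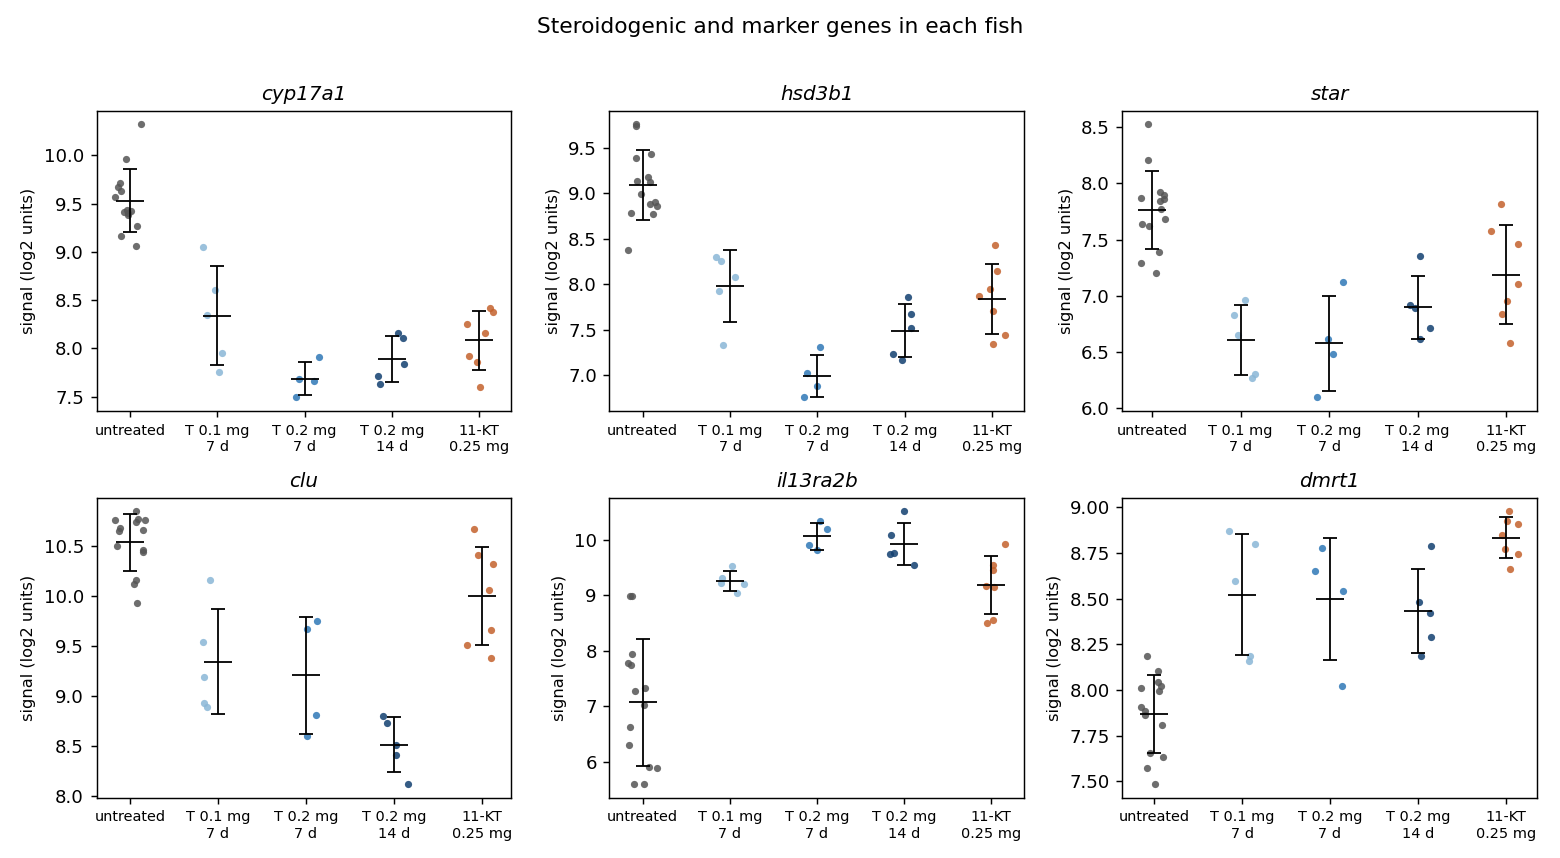
Signal (log2 units) of 6 genes in each fish, by treatment group, with the mean and SD as bars. The genes cyp17a1, hsd3b1 and star were lower in each treated group than in the 14 untreated fish, il13ra2b and dmrt1 were higher, and clu was lower with testosterone, reaching 8.51 ± 0.27 at 14 days.

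In total 40 clones rose and 12 fell in all 4 comparisons with untreated fish, against 0.00489 and 0.000332 for independent lists. The 4 comparisons share the untreated fish, so their lists are not independent. All 4 treated groups also carried an implant, so a shared change may come from the implant as well as the hormone. The overlap is limited by the calls with testosterone 0.1 mg, of which 75 of 259 held without the 4 arrays under 0.93, 88 with only the arrays compared, 102 with array weights and 19 with the replicate number as a block, where fewer than 40 clones can have risen in all 4. Between testosterone 0.2 mg for 7 days and 11-ketotestosterone, 99 clones rose in both and 25 fell in both, against 6.68 and 1.18 for independent lists, and 0 of the clones called in both went opposite ways. Their changes correlated over clones at r = 0.567, and clones are not independent replicates. Because both share the untreated fish, simulated unchanged groups gave r = 0.273 (highest 0.312) and a covariance of 0.0052 against 0.0301 observed. With the untreated fish split into 2 sets of 7, r was 0.474 and 0.456. Clones moved together in the real fish, with residuals of same-number arrays in different groups correlated at -0.308 to 0.383. The simulated ranges may therefore be too narrow. Between testosterone for 14 days and 11-ketotestosterone, 107 rose in both (6.87 for independent lists) and 17 fell in both (0.59), with r = 0.619 against 0.296 simulated. Between the 7-day and 14-day groups at 0.2 mg, 194 rose in both (24.11 for independent lists), 59 fell in both (6.56) and 10 went opposite ways, with r = 0.528 against 0.24 simulated.

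**Figure D2:**
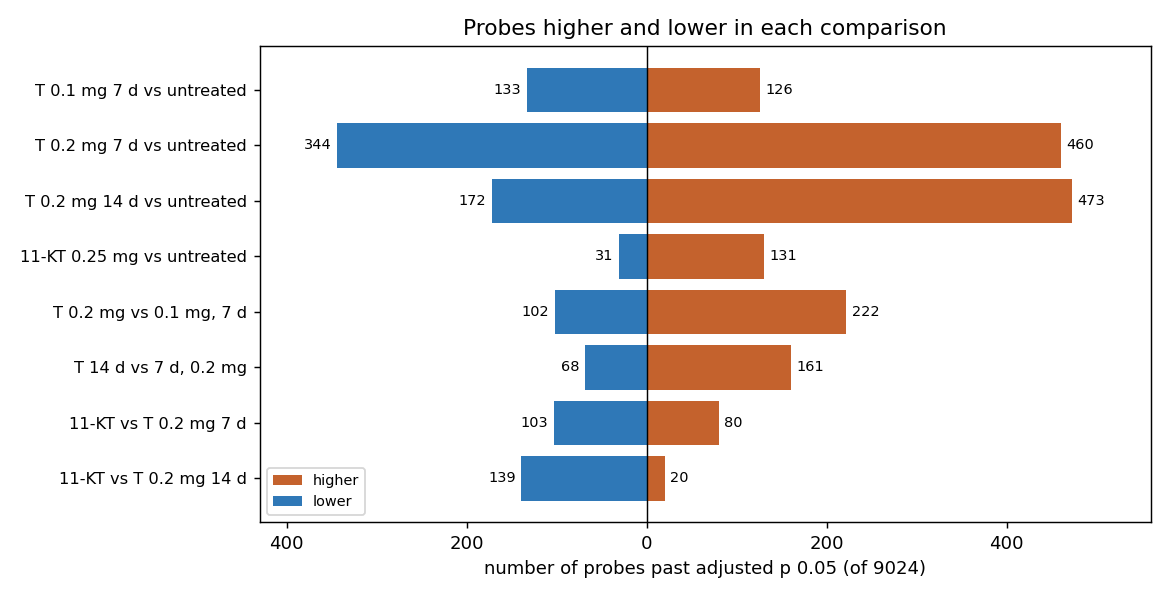
Number of clones that rose (bars right of 0) or fell (bars left of 0) at an adjusted p under 0.05 in each comparison of 9024 clones. Among the 4 treated groups, each against untreated fish, the 2 with testosterone 0.2 mg had the highest counts, 460 up and 344 down at 7 days and 473 up and 172 down at 14 days.

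With testosterone 0.1 mg for 7 days, clu, cyp17a1, star and hsd3b1 fell, and il13ra2b, slc39a1, cahz and dmrt1 rose. The secreted chaperone clu, abundant in Sertoli cells, was at -1.20 ± 0.20 (adjusted p = 0.000356). The other large falls among named genes were cyp17a1 at -1.19 ± 0.16 (adjusted p = 3.8e-05), star at -1.16 ± 0.18 (adjusted p = 0.000116) and hsd3b1 at -1.12 ± 0.18 (adjusted p = 0.000192). All 5 fish lay below the untreated mean for each of these 4 genes. Rising genes included il13ra2b at 2.19 ± 0.38 (adjusted p = 0.000631), slc39a1 at 1.01 ± 0.17 (adjusted p = 0.000396), cahz at 0.85 ± 0.15 (adjusted p = 0.000637) and dmrt1 at 0.65 ± 0.12 (adjusted p = 0.00147), each higher than the untreated mean in 5 of 5 fish. The unnamed clone tcay0019.j.13 fell by 1.37 ± 0.18 (adjusted p = 3.8e-05). In all, 259 clones changed, 126 up and 133 down, and this balance depended on the setting: 119 up and 57 down with array weights, 55 and 36 with only the arrays compared, 72 and 50 without the 4 arrays under 0.93, 73 and 71 with the globin covariate, and 9 and 10 with the replicate number as a block. Of the 6 Leydig cell genes measured, 3 fell (3 adjusted over the list alone), and of the 8 steroidogenesis genes, which include those 6, the same 3 (3 adjusted over the list alone). The Leydig list lay lower by camera (adjusted p = 2.52e-05), with adjusted p = 0.0562 with an estimated correlation. The steroidogenesis list did too (adjusted p = 0.000309), with adjusted p = 0.0697 with an estimated correlation. Of the 5 Sertoli cell genes dmrt1 rose and clu fell (1 and 1 adjusted over the list alone), and 0 of 6 genes for receptors and steroid-binding globulins changed in limma (0 adjusted over the list alone and 0 at an unadjusted p under 0.05). Smaller calls were jun at 0.53 ± 0.15 (adjusted p = 0.0469), with 4 of 5 fish above the untreated mean, and pfn1, an actin-binding protein, at 0.55 ± 0.14 (adjusted p = 0.0183). Others were arpc3, of the actin-nucleating complex, at -0.53 ± 0.12 (adjusted p = 0.0137), eif5a at -0.51 ± 0.12 (adjusted p = 0.014) and cct8, of a cytosolic chaperonin, at -0.45 ± 0.11 (adjusted p = 0.0183). These 5 calls were lost when only the arrays of the 2 groups were fitted, which left 91 clones in all. Without fish 4 of this group adjusted p was 0.0772 for arpc3, 0.0724 for eif5a and 0.0718 for cct8, without fish 1 it was 0.121 for pfn1, and jun was lost without any 1 of 11 untreated fish and without fish 2, 3 or 4 of this group (adjusted p = 0.0502 to 0.166). Without the 4 arrays under 0.93, of which 2 are from this group, 122 clones were called.

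With testosterone 0.2 mg for 7 days, hsd3b1 and cyp17a1 fell in all 4 fish below each untreated fish, and 46 named genes rose while 19 fell. The gene hsd3b1 fell by 2.10 ± 0.19 (adjusted p = 2.56e-10), from 9.09 ± 0.39 to 6.99 ± 0.23, and cyp17a1 fell by 1.84 ± 0.18 (adjusted p = 8.66e-10). Further falls were clu at -1.33 ± 0.21 (adjusted p = 2.77e-05), star at -1.19 ± 0.19 (adjusted p = 3.47e-05), igfbp7 at -0.79 ± 0.18 (adjusted p = 0.00383) and cyp11b, a hydroxylase on the path to 11-ketotestosterone, at -0.62 ± 0.15 (adjusted p = 0.00657). Rising genes included il13ra2b at 2.99 ± 0.41 (adjusted p = 1.85e-06), jun at 1.91 ± 0.17 (adjusted p = 9.6e-11), slc39a1 at 1.83 ± 0.18 and cahz at 1.48 ± 0.16. Others were the fatty acid-binding proteins fabp3 at 1.71 ± 0.22 and fabp7b at 1.09 ± 0.18, the chemokine cxcl14 at 1.12 ± 0.19, and glulb, a glutamine synthetase, at 1.08 ± 0.20, each with an adjusted p of 0.000188 or less. All 4 fish lay above each untreated fish for il13ra2b, jun, slc39a1, fabp3, cahz and cxcl14. The largest change of any clone was in tcbk0013.j.13, unnamed, which rose by 5.23 ± 0.28 (adjusted p = 3.29e-17), in 4 of 4 fish, and tcbk0026.e.15, also unnamed, rose by 3.49 ± 0.26 (adjusted p = 8.51e-13).

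Of 9024 clones 804 changed in this group, 460 up and 344 down. Of the 6 Leydig cell genes 5 fell (5 adjusted over the list alone): cyp17a1, hsd3b1, star, cyp11b and hsd11b2, the last at -0.82 ± 0.21 (adjusted p = 0.0108). The luteinizing hormone receptor gene lhcgr was at 0.12 ± 0.18 (adjusted p = 0.77). The list lay lower (camera adjusted p = 3.12e-07, and adjusted p = 0.0360 with an estimated correlation). The 8 steroidogenesis genes add tspo at 0.12 ± 0.10 (adjusted p = 0.535) and cbr1 at 0.10 ± 0.12 (adjusted p = 0.688), and 5 of them fell (5 adjusted over the list alone; camera adjusted p = 2.52e-05, and adjusted p = 0.0449 with an estimated correlation). Without the 4 arrays under 0.93 both lists had an adjusted p of 0.0921 with an estimated correlation. Of 6 genes for receptors and steroid-binding globulins the estrogen receptor gene esr1 rose at 0.43 ± 0.14 (adjusted p = 0.0458), 1 adjusted over the list alone, while nr3c1, the globulin genes shbg and shbgb, and esr2a were at -0.15, 0.09, -0.22 and 0.20. Of 5 Sertoli cell genes dmrt1 and cxcl14 rose and clu fell (2 and 1 adjusted over the list alone). All 3 erythrocyte genes rose (3 adjusted over the list alone), among them the globin chains hba1 at 1.20 ± 0.28 (adjusted p = 0.00421) and hbb1 at 1.19 ± 0.28 (adjusted p = 0.00419). The mean globin signal of 8 clones lay 0.915 log2 units above that of the untreated fish here, and 0.403, 0.276 and 0.174 above it with testosterone 0.1 mg, testosterone for 14 days and 11-ketotestosterone. Of 12 liver and plasma genes 2 rose and 1 fell (4 and 1 adjusted over the list alone), including lect2 at 1.04 ± 0.21 (adjusted p = 0.000681) and c9, a complement component, at 0.62 ± 0.18 (adjusted p = 0.021).

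Some calls of the 0.2 mg 7-day group were uneven among its 4 fish or were lost without 1 of them. The stanniocalcin gene stc, a hormone of calcium balance in fish, was at 1.40 ± 0.28 (adjusted p = 0.000751) with values of 9.08, 8.11, 5.71 and 6.05 in the 4 fish. The falls of casp9, a caspase, at -1.21 ± 0.34 (adjusted p = 0.0184) and cyp1a3, a cytochrome P450, at -0.81 ± 0.21 (adjusted p = 0.0101) went to -0.20 and -0.30 without fish 4 (adjusted p = 0.402 and 0.30). Without fish 1 the fall of inh went from -0.96 ± 0.22 to -0.65 (adjusted p = 0.0898), that of hsd11b2 to -0.61 (adjusted p = 0.141) and that of cyp11b to -0.51 (adjusted p = 0.0793), though all 4 fish lay below each untreated fish for cyp11b. The rises of hba1 and hbb1 went to 0.90 and 0.92 without it (adjusted p = 0.0829 and 0.0745). Without fish 4 hsd11b2 was at -0.71 (adjusted p = 0.0798), and c9 was at 0.46 without fish 3 (adjusted p = 0.135) and 0.63 without fish 4 (adjusted p = 0.0583). The call of esr1 was lost without any 1 of 13 fish (adjusted p = 0.0519 to 0.255). The count fell to 415 without fish 1 and 473 without fish 4.

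With the mean globin signal as a covariate, 227 clones changed with testosterone 0.2 mg for 7 days, and the median standard error went from 0.1296 to 0.1583. Named genes no longer past the threshold included stc at 0.95 ± 0.32, casp9 at -0.98 ± 0.42, cyp1a3 at -0.76 ± 0.26, inh at -0.78 ± 0.27, hsd11b2 at -0.53 ± 0.25, cyp11b at -0.54 ± 0.19 and esr1 at 0.39 ± 0.17. Each had a smaller change and a larger standard error than without the covariate. The globin genes themselves make up that signal and cannot be judged with it.

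With testosterone 0.2 mg for 14 days, collagen genes rose, and clu, cyp17a1, hsd3b1 and star fell. The collagen chain gene col1a1 rose by 1.06 ± 0.15 (adjusted p = 3.38e-06), from 11.12 ± 0.34 to 12.18 ± 0.13, and col1a1b by 1.08 ± 0.17 (adjusted p = 1.13e-05) on 1 of its 2 clones. All 3 clones of hsp47, a chaperone of collagen, rose, 1 of them by 0.87 ± 0.16 (adjusted p = 0.000206). Other rising genes were il13ra2b at 2.85 ± 0.38 (adjusted p = 6.54e-07), cxcl14 at 1.84 ± 0.17 (adjusted p = 7.28e-10), fabp3 at 1.68 ± 0.20, leg at 1.41 ± 0.16, slc39a1 at 1.36 ± 0.17 and s10i at 1.32 ± 0.18. Next came pomc, the precursor of corticotropin, at 1.28 ± 0.22 (adjusted p = 6.37e-05), jun at 1.27 ± 0.15, cahz at 1.27 ± 0.15 and csrp1 at 1.17 ± 0.19. The gene clu fell by 2.03 ± 0.20 (adjusted p = 1.14e-09), and cyp17a1 was at -1.64 ± 0.16 (adjusted p = 2.01e-09), hsd3b1 at -1.61 ± 0.18 (adjusted p = 1.73e-08) and star at -0.87 ± 0.18 (adjusted p = 0.000775), each below the untreated mean in 5 of 5 fish. The unnamed clone tcba0024.p.18 fell by 2.18 ± 0.24 (adjusted p = 1.26e-08), and tcbk0013.j.13 rose by 3.56 ± 0.25 (adjusted p = 1.35e-12).

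In this group 645 clones changed, 473 up and 172 down. Of the 4 extracellular matrix genes col1a1, col1a1b and col1a2 rose (3 adjusted over the list alone). Of the 6 Leydig cell genes 3 fell (4 adjusted over the list alone; camera adjusted p = 0.000253, and adjusted p = 0.0867 with an estimated correlation). The same 3 of 8 steroidogenesis genes fell (4 adjusted over the list alone; camera adjusted p = 0.000253, and adjusted p = 0.0697 with an estimated correlation). The other members were cyp11b at -0.34 ± 0.14 (adjusted p = 0.155), hsd11b2 at 0.09 ± 0.20, lhcgr at 0.17 ± 0.17, tspo at -0.11 ± 0.09 and cbr1 at -0.16 ± 0.11. Of 5 Sertoli cell genes dmrt1, cxcl14 and krt18 rose and clu fell (4 and 1 adjusted over the list alone). Of 6 genes for receptors and steroid-binding globulins esr2a, an estrogen receptor gene, rose at 0.43 ± 0.13 (adjusted p = 0.0303), 1 adjusted over the list alone. Of 6 ribosomal protein genes rps20 and rps24 fell (3 adjusted over the list alone), at -0.40 ± 0.12 (adjusted p = 0.0394) and -0.37 ± 0.12 (adjusted p = 0.0489). Of 5 oxidative phosphorylation genes ndufa2 rose in the mean of its 2 clones (1 adjusted over the list alone), whose changes were opposite in sign, 0.79 and -0.06. The complement receptor gene c3ar1 fell by 1.65 ± 0.45 (adjusted p = 0.0157), and this call was lost without fish 3 or fish 5 of the group (adjusted p = 0.0575 and 0.0732). The call of esr2a was lost without fish 1, 2, 3 or 4 of the group (adjusted p = 0.0697 to 0.101) and that of krt18 without fish 2, 3 or 4 (adjusted p = 0.0629 to 0.13). The calls of rps20 and rps24 were lost without any 1 of 7 and any 1 of 15 fish (adjusted p up to 0.162 and 0.223). The count was 983 without the 4 arrays under 0.93, 610 up and 373 down, and 1438 with array weights, 763 up and 675 down.

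With 11-ketotestosterone (0.25 mg, 7 or 14 days), cyp17a1 and hsd3b1 fell, and il13ra2b and dmrt1 were among 10 named genes that rose. The gene cyp17a1 fell by 1.45 ± 0.14 (adjusted p = 9.23e-09) and hsd3b1 by 1.25 ± 0.16 (adjusted p = 7.37e-07), each in 7 of 7 fish, with cyp17a1 below each untreated fish. Rising genes included il13ra2b at 2.11 ± 0.34 (adjusted p = 4.64e-05), slc39a1 at 1.42 ± 0.15 (adjusted p = 2.26e-08), fabp3 at 1.17 ± 0.18 (adjusted p = 2.55e-05), cxcl14 at 1.13 ± 0.15 (adjusted p = 2.91e-06) and jun at 1.09 ± 0.14 (adjusted p = 6.8e-07). Others included dmrt1 at 0.96 ± 0.11 (adjusted p = 8.14e-08), cahz at 0.67 ± 0.13 (adjusted p = 0.00111) and acbp, an acyl-CoA-binding protein, at 0.57 ± 0.13 (adjusted p = 0.00743). All 7 fish lay above each untreated fish for slc39a1, jun, cxcl14 and dmrt1. The gene clu was at -0.54 ± 0.17 (adjusted p = 0.129). In all, 162 clones changed, 131 up and 31 down.

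Of the 6 Leydig cell genes cyp17a1, hsd3b1 and star fell with 11-ketotestosterone for 7 or 14 days (4 fell and 1 rose adjusted over the list alone; camera adjusted p = 3.86e-05, and adjusted p = 0.0625 with an estimated correlation). The same 3 of 8 steroidogenesis genes fell (4 fell and 1 rose adjusted over the list alone; camera adjusted p = 4.48e-05, and adjusted p = 0.0503 with an estimated correlation). The other members were cyp11b at -0.41 ± 0.12 (adjusted p = 0.0931), lhcgr at 0.44 ± 0.15 (adjusted p = 0.16), hsd11b2 at 0.00 ± 0.17, tspo at -0.06 ± 0.08 and cbr1 at -0.16 ± 0.09. Of 5 Sertoli cell genes cxcl14 and dmrt1 rose (2 rose and 1 fell adjusted over the list alone). The Sertoli list lay higher by camera (adjusted p = 0.0498) and by its mean of 0.29, but its median was -0.04, and adjusted p = 0.165 with an estimated correlation. In limma 0 of 6 genes for receptors and steroid-binding globulins changed (1 rose adjusted over the list alone, and 1 at an unadjusted p under 0.05). The plasma retinol carrier rbp4 was at -0.77 ± 0.21 (adjusted p = 0.0405). It was the 1 of 2 retinoid pathway genes that fell (1 adjusted over the list alone), and the 1 of 12 liver and plasma genes (1 adjusted over the list alone). The call of star, -0.58 ± 0.16 (adjusted p = 0.0438), was lost without untreated fish 1, 3, 4, 7, 8, 9, 11, 13 or 14 or treated fish 2, 4, 5 or 6 (adjusted p = 0.0522 to 0.169). That of rbp4 was lost without untreated fish 2, 3, 10 or 14 or treated fish 1, 2, 3, 4 or 6 (adjusted p = 0.0594 to 0.108). The count was 276 without the 4 arrays under 0.93, 190 up and 86 down, and 311 with array weights, 201 up and 110 down.

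At 7 days, the dose comparison set testosterone 0.2 mg (n = 4) beside 0.1 mg (n = 5). The unnamed clone tcbk0013.j.13 was higher at 0.2 mg by 4.76 ± 0.33 (adjusted p = 1.99e-13) and jun by 1.38 ± 0.20 (adjusted p = 1.86e-05). Also higher were fabp3 by 1.11 ± 0.26 (adjusted p = 0.0114), acbp by 0.81 ± 0.19 (adjusted p = 0.0106) and rtnanos3, an RNA-binding protein of germ cells, by 0.65 ± 0.16 (adjusted p = 0.0169). The gene hsd3b1 was lower at 0.2 mg, -0.99 ± 0.23 (adjusted p = 0.0106), while cyp17a1 was at -0.65 ± 0.21 (adjusted p = 0.0696), star at -0.03 ± 0.23 (adjusted p = 0.97) and il13ra2b at 0.80 ± 0.49 (adjusted p = 0.367). In all, 324 clones differed, 222 higher and 102 lower at 0.2 mg. Mean globin signal differed between these groups, 0.915 against 0.403 log2 units above the untreated fish, and with it as a covariate 122 clones differed, 94 higher and 28 lower. The Leydig list lay lower at 0.2 mg (camera adjusted p = 0.0207, with 2 of 6 genes lower and 3 adjusted over the list alone), and adjusted p = 0.368 with an estimated correlation. Of 8 steroidogenesis genes 2 were lower (2 adjusted over the list alone; camera adjusted p = 0.0915). All 3 proteasome genes were higher adjusted over the list alone and at an unadjusted p under 0.05, and 0 of 3 over the 591 genes. The differences of inh, -1.20 ± 0.26 (adjusted p = 0.006), and acbp were lost without fish 1 of the 0.2 mg group (adjusted p = 0.0676 and 0.0598). Without the 4 arrays under 0.93 those of hsd3b1, fabp3 and acbp were lost. The count was 121 without fish 1 and 185 without fish 4 of the 0.2 mg group, 141 without the 4 arrays, and 77 when only the arrays of the 2 groups were fitted.

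At 0.2 mg, the time comparison set 14 days (n = 5) beside 7 days (n = 4) of testosterone. The gene hsp47 was higher at 14 days at 0.71 ± 0.14 (adjusted p = 0.00349), and col1a1 at 0.82 ± 0.20 (adjusted p = 0.0155). Also higher were ssr1 at 0.86 ± 0.16 (adjusted p = 0.00138), leg at 0.82 ± 0.20 (adjusted p = 0.019), pomc at 1.12 ± 0.28 (adjusted p = 0.0228) and igfbp7, an IGF-binding protein, at 0.85 ± 0.22 (adjusted p = 0.0238). The gene stc was lower at -1.48 ± 0.33 (adjusted p = 0.00918), as was the unnamed clone tcbk0013.j.13 at -1.67 ± 0.33 (adjusted p = 0.00235). The genes cyp17a1 at 0.20 ± 0.21, hsd3b1 at 0.50 ± 0.23 and star at 0.32 ± 0.23 did not pass the test. In all, 229 clones differed, 161 higher and 68 lower at 14 days. Mean globin signal differed between these groups, 0.276 log2 units above the untreated fish at 14 days and 0.915 at 7 days. With it as a covariate 172 clones differed, 140 higher and 32 lower. Of the 4 extracellular matrix genes col1a1 was higher (3 adjusted over the list alone). Of 6 Leydig cell genes hsd11b2, which makes the oxo group of 11-ketotestosterone, was higher at 0.90 ± 0.25 (adjusted p = 0.0404), 1 adjusted over the list alone (camera adjusted p = 0.0268, and adjusted p = 0.385 with an estimated correlation). It was also the 1 of 8 steroidogenesis genes that was higher (1 adjusted over the list alone; camera adjusted p = 0.311). The untreated fish carry no duration, so a change with time alone was not separable. The call of col1a1 was lost without fish 1 or 3 of the 7-day group (adjusted p = 0.0733 and 0.0545) and that of stc without fish 1 or 2 of it (adjusted p = 0.105 and 0.0569). That of pomc was lost without fish 1 or 2 of either group (adjusted p = 0.0644 to 0.0685), that of igfbp7 without fish 2 or 3 of the 7-day or fish 1 or 2 of the 14-day group (adjusted p = 0.052 to 0.103), and that of hsd11b2 without any 1 of 7 fish (adjusted p = 0.0574 to 0.247). The call of tcbk0013.j.13 was lost when only the arrays of the 2 groups were fitted. The count was 105 without fish 1 of the 7-day group and 111 without fish 2 of the 14-day group.

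**Figure D3:**
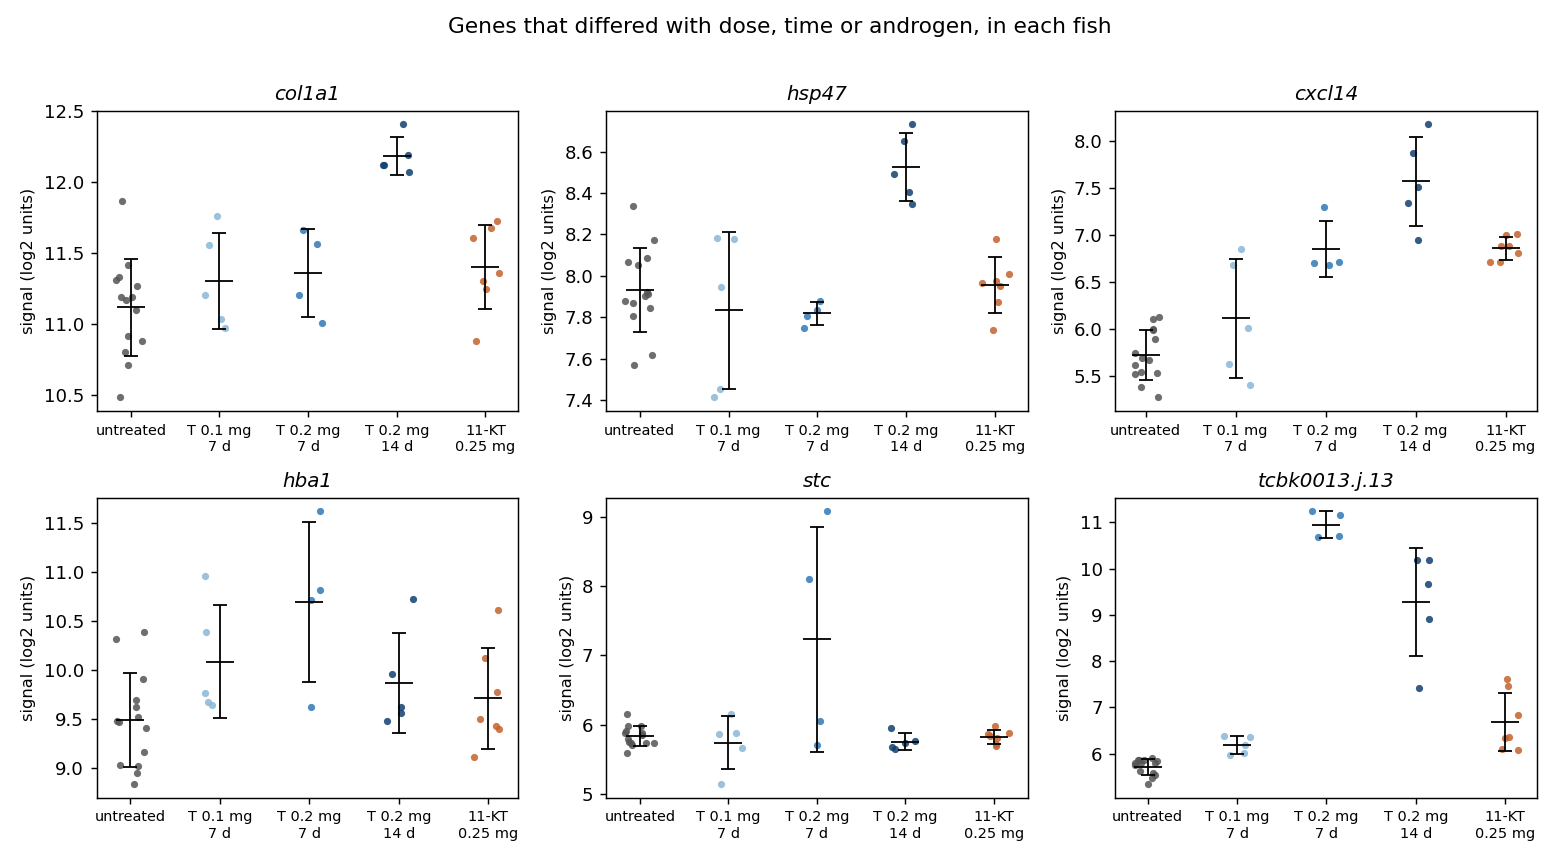
Signal (log2 units) in each fish of col1a1, hsp47 (1 clone), cxcl14, hba1, stc and the unnamed clone tcbk0013.j.13, with the mean and SD of each group as bars. The signal of col1a1 was 12.18 ± 0.13 at 14 days against 11.36 ± 0.31 at 7 days, and stc was high in 2 of the 4 fish with testosterone 0.2 mg for 7 days.

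The 2 androgens were compared at doses that differ, 0.25 mg of 11-ketotestosterone (n = 7) and 0.2 mg of testosterone, and at durations that match for only 1 of the 2 testosterone groups, depending on which label holds. Against testosterone for 7 days (n = 4), the clone tcbk0013.j.13 was lower with 11-ketotestosterone, -4.26 ± 0.31 (95% interval -4.88 to -3.64, adjusted p = 7.91e-13). Lower genes were cahz at -0.81 ± 0.18 (95% interval -1.17 to -0.45, adjusted p = 0.00896) and jun at -0.82 ± 0.18 (95% interval -1.19 to -0.45, adjusted p = 0.0109). Others were lect2, a chemotaxin, at -1.04 ± 0.23 (95% interval -1.50 to -0.57, adjusted p = 0.00999) and rtnanos3 at -0.64 ± 0.15 (95% interval -0.94 to -0.34, adjusted p = 0.0153). The gene inh was higher at 1.31 ± 0.24 (95% interval 0.82 to 1.80, adjusted p = 0.0017). So was hsd3b1 at 0.85 ± 0.21 (95% interval 0.42 to 1.28, adjusted p = 0.0264). For cyp17a1 the difference was 0.40 ± 0.20 (95% interval 0.00 to 0.80, adjusted p = 0.342), for star 0.61 ± 0.21 (95% interval 0.18 to 1.04, adjusted p = 0.137) and for dmrt1 0.34 ± 0.15 (95% interval 0.04 to 0.63, adjusted p = 0.264). Of 9024 clones 183 differed, 80 higher and 103 lower with 11-ketotestosterone. Of the 6 Leydig cell genes 2 were higher (3 adjusted over the list alone; camera adjusted p = 0.000130, and adjusted p = 0.0721 with an estimated correlation), and of the 8 steroidogenesis genes the same 2 (3 adjusted over the list alone; camera adjusted p = 0.0148, and adjusted p = 0.250 with an estimated correlation). With the globin covariate 44 clones differed, and cahz, jun and hsd3b1, then at -0.47 ± 0.16, -0.60 ± 0.19 and 0.71 ± 0.24, were not past the threshold. Without testosterone fish 1 adjusted p was 0.0667 for cahz, 0.0677 for jun and 0.115 for hsd3b1, and without fish 3 it was 0.0568 for lect2. For hsd3b1 it was also 0.0787 and 0.0792 without testosterone fish 2 or 4 and 0.0505 and 0.0725 without 11-ketotestosterone fish 4 or 7, and for rtnanos3 0.0561 and 0.0572 without testosterone fish 2 or 4. Leaving out testosterone fish 1, 3 or 4 gave 54, 275 and 63 clones, and leaving out 11-ketotestosterone fish 2, 6 or 7 gave 118, 117 and 83.

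Against testosterone for 14 days (n = 5), clu was higher with 11-ketotestosterone by 1.49 ± 0.22 (95% interval 1.04 to 1.94, adjusted p = 3.78e-05). So was the clone tcba0024.p.18 by 1.86 ± 0.27 (95% interval 1.33 to 2.40, adjusted p = 1.91e-05). Lower genes were s10i at -1.21 ± 0.21 (95% interval -1.63 to -0.79, adjusted p = 0.000335), rbp4 at -1.19 ± 0.26 (95% interval -1.72 to -0.66, adjusted p = 0.00722) and leg at -1.10 ± 0.18 (95% interval -1.46 to -0.74, adjusted p = 0.000137). Further ones were c4b, a complement gene, at -0.86 ± 0.15 (95% interval -1.17 to -0.55, adjusted p = 0.000527) and col1a1 at -0.78 ± 0.17 (95% interval -1.13 to -0.43, adjusted p = 0.00722). The clone tcbk0013.j.13 was lower too, -2.60 ± 0.29 (95% interval -3.17 to -2.02, adjusted p = 4.28e-07). The steroid synthesis genes differed by 0.20 ± 0.18 (95% interval -0.18 to 0.57, adjusted p = 0.858) for cyp17a1, 0.35 ± 0.20 (95% interval -0.05 to 0.75, adjusted p = 0.614) for hsd3b1 and 0.29 ± 0.20 (95% interval -0.11 to 0.70, adjusted p = 0.721) for star. In limma 0 of the 6 Leydig cell genes and 0 of the 8 steroidogenesis genes differed (0 adjusted over the list alone and 0 at an unadjusted p under 0.05). In all, 159 clones differed, 20 higher and 139 lower with 11-ketotestosterone. Without testosterone fish 2 adjusted p for rbp4 was 0.0567 and 90 clones differed, and fitting only the arrays of the 2 groups gave 262.

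**Figure D4:**
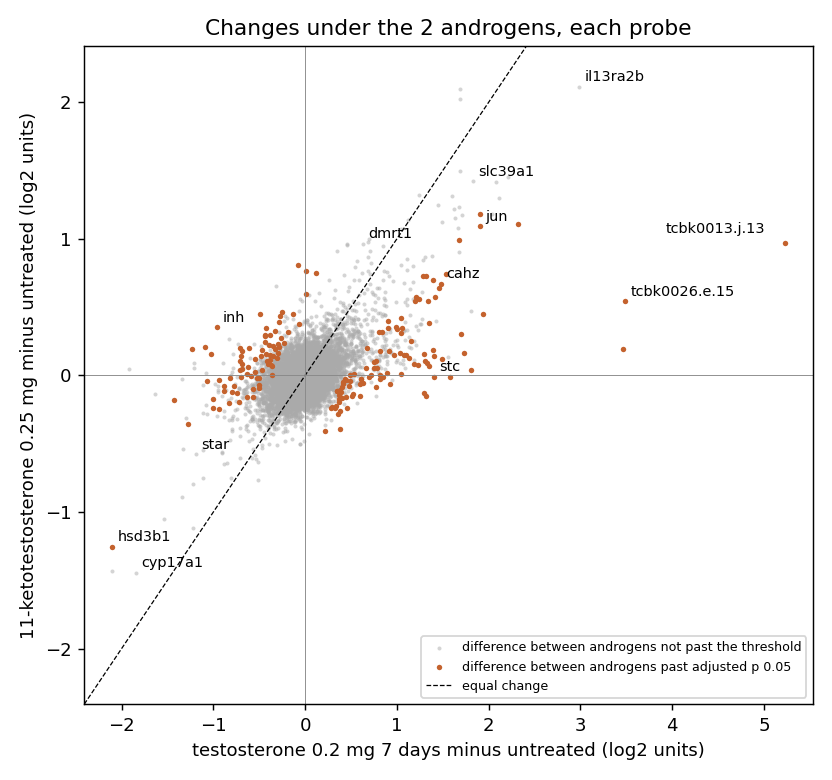
Change of each of 9024 clones with testosterone 0.2 mg for 7 days (x, log2 units) against its change with 11-ketotestosterone 0.25 mg (y, log2 units), both relative to the same 14 untreated fish, with clones that differed between the androgens in orange and equal change as a dashed line. The clone tcbk0013.j.13 lies at 5.23 and 0.97, and il13ra2b at 2.99 and 2.11.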

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

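The tests of a Leydig cell share, of 1 weak array and of liver RNA were chosen only after the results were seen, and the 2 alternatives used here, leaving out 4 arrays and the globin covariate, were chosen after seeing the data.

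The signals of cyp17a1, hsd3b1 and star were lower in all 4 treated groups, 12 calls in all. Fewer Leydig cells, as the only change, would lower all 6 Leydig cell genes by a common amount. Their changes were unequal in each treated group (highest of the 4 adjusted p = 5.21e-07), ranging from -2.10 to 0.12 with testosterone 0.2 mg for 7 days. The top of that range was lhcgr, at a mean of 6.62 (percentile 47.1 of clones), and a dimmer clone may show less of a fall. Over all treated fish the brighter genes, at percentiles 88.3 to 94.8, also differed: cyp17a1 at -1.507, hsd3b1 at -1.467, cyp11b at -0.378 and hsd11b2 at -0.218. This argues against a lower share of Leydig cells alone, as far as the clones respond alike to RNA. All 12 calls held without the 4 arrays under 0.93, and 11 of 12 held with the globin covariate, which argues against those arrays and against blood content as the cause. The exception was star with 11-ketotestosterone (duration uncertain), which went from -0.58 ± 0.16 (adjusted p = 0.0438) to -0.54 ± 0.16 (adjusted p = 0.076), so its call ended through a slightly smaller change near the threshold. The hormone treatment may explain the lower signals, a hypothesis found and tested on the same data. No group had an implant without hormone, so for a change shared by all 4 treated groups the implant and the hormone cannot be told apart. A lower share of Leydig cells together with other changes, or with expression in other cells, also stays open, since cyp11b (-0.62 ± 0.15) and hsd11b2 (-0.82 ± 0.21) fell too with testosterone 0.2 mg for 7 days.

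More clones changed with testosterone 0.2 mg for 7 days than in the other treated groups, 804 against 259, 645 and 162, but the 14-day group had more with array weights (1438 against 1007), without the 4 arrays (983 against 608), with the replicate number as a block (370 against 259), with only the arrays compared (850 against 829) and with the globin covariate (582 against 227). Blood content may contribute: globin signal was higher in this group, but the slopes on globin signal among untreated fish correlated with its changes at r = 0.128 only, against up to 0.332 for another group. The globin covariate also raised the median standard error from 0.1296 to 0.1583. With 1 weak array as the cause the count would fall below 645 only without fish 1, and it was 415 without fish 1, 473 without fish 4, 684 without fish 2 and 842 without fish 3. The hormone dose, blood content, single fish and the processing cannot be told apart here as the source of this order, since the group holds 4 fish and globin signal differs with the group.

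The unnamed clones tcbk0013.j.13 and tcbk0026.e.15 were far higher with testosterone 0.2 mg for 7 days, by 4.358 log2 units on average. Liver RNA in the tissue would raise all abundant liver transcripts, and the 12 liver and plasma genes rose by 0.233 on average (95% interval 0.019 to 0.446), with lect2 at 1.04 ± 0.21 and rbp4 at -0.52 ± 0.25. The interval lay below 1 log2 unit, the cut-off chosen, and above 0. This argues against a share of liver RNA that raises the list by 1 log2 unit. A smaller share stays open, since it would raise genes with their own testis signal little. The clone tcbk0013.j.13 was dim in untreated fish, at 5.34 to 5.91. With the globin covariate the 2 clones were still higher by 4.156 log2 units, which argues against blood content. A direct response to testosterone may explain the rise, as may a hormone-induced transcript of a small fixed share of another cell type, which these values leave open.

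Each comparison was set beside 100 splits of the same fish into groups of the same sizes, the real one included, and 1 split, the real one, gave as many calls in each case. The real count and the highest of the other splits were 259 and 210 for testosterone 0.1 mg, 804 and 15 for 0.2 mg for 7 days, 645 and 154 for 14 days, and 162 and 2 for 11-ketotestosterone. They were 845 and 135 for the mean of the testosterone groups, 324 and 211 for the doses, and 229 and 46 for the durations. They were 183 and 13 for 11-ketotestosterone against 7 days of testosterone, 159 and 12 against 14 days, 1073 and 27 for the F test, and 15 and 11 for the gene lists. A share of 1 in 100 is the lowest that 100 splits can give, and it was not adjusted over the comparisons. A chance split of the fish is therefore unlikely for each and not excluded. The margin was small for testosterone 0.1 mg, the doses and the gene lists.

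Changes from untreated fish differed between treated groups by tests of the difference itself. Between the 2 doses 324 clones differed, with jun at 1.38 ± 0.20 (adjusted p = 1.86e-05), and between the 2 durations 229 differed, with hsp47 at 0.71 ± 0.14 (adjusted p = 0.00349). Between 11-ketotestosterone and 7 days of testosterone 183 differed, with tcbk0013.j.13 at -4.26 ± 0.31 (adjusted p = 7.91e-13). Of all clones 12 rose in 1 treated group and fell in another, 10 of them lower at 7 and higher at 14 days of testosterone 0.2 mg. None of these 12 has a gene name here.

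In 21 of 280 groups of 4 to 7 fish, 1 fish lay far from the others of its group, against 14.0 expected by chance at 5%. With testosterone 0.2 mg for 7 days these were fish 4 for cxcl14 (7.30), casp9 (3.74), cyp1a3 (4.23) and hif1a (6.37), and fish 3 for rbp4 (7.15). With testosterone 0.2 mg for 14 days they were fish 1 for jun (6.68) and rps24 (6.52), fish 3 for rtnanos3 (6.06), and fish 5 for esr2a (5.14). Fish 4 of that group lay apart for hbb4 (10.95), c3ar1 (7.59), acbp (10.39) and the clone tcay0019.j.13 (6.79). With testosterone 0.1 mg they were fish 3 for hbb1 (11.56), lect2 (6.19) and ghr1 (7.35), and fish 4 for ipyr (7.96). With 11-ketotestosterone they were fish 7 for fabp3 (10.77), fish 1 for col1a1b (10.25) and fish 4 for the clone tcbk0026.e.15 (7.72). The array of that fish 4 also had a median correlation with the other arrays of 0.948, apart from the rest of its group.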

How the results depend on the processing

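Leaving out the 4 arrays under 0.93, the globin covariate and the added list spellings were chosen after seeing the data. A second quantile normalization and centring on array medians moved nothing, since the arrays already shared 1 set of values, so they say nothing about stability, and a pseudocount does not apply to log values. Leaving out the dimmest 25% of clones and eBayes with trend and robust kept each count within 1.5 times. They covered 523 and 661 named differences, among which 0 and 6 calls were lost. Of 661 differences of named genes, none reversed under any alternative. Only the 215 past the threshold had a call to lose. Calls lost were 81 with the replicate number as a block, 63 with the globin covariate, 45 without the 4 arrays, 45 with only the arrays compared and 19 with array weights. With genes in place of clones, which covered 625 of the differences, 8 calls were lost. Fitting only the arrays compared gave 91 clones for testosterone 0.1 mg against untreated, 77 for the doses and 262 for 11-ketotestosterone against 14 days of testosterone. Array weights gave 1438 for testosterone for 14 days and 311 for 11-ketotestosterone against untreated, 176 for the doses, 455 for the durations, 291 and 420 for 11-ketotestosterone against 7 and 14 days of testosterone, and 1643 for the F test. The replicate number as a block gave 19, 259, 370 and 243 for testosterone 0.1 mg, 0.2 mg for 7 days, 0.2 mg for 14 days and their mean, 183 for the doses, 145 for the durations, 72 and 97 for the androgens, and 436 for the F test. Residuals of 48 same-number pairs correlated at -0.001 on average against 0.001 for other pairs, so no pairing showed on average. Between 2 groups the same-number mean ran from -0.066 to 0.102, the latter for testosterone 0.1 mg and 11-ketotestosterone. Of 28 arrays 8 had their best match under their own number, and the number expected without pairing was not computed. Pairing of some fish is therefore not excluded. Without the 4 arrays the counts were 122 for testosterone 0.1 mg, 983 for 14 days, 276 for 11-ketotestosterone, 141 for the doses and 248 for 11-ketotestosterone against 14 days. With the globin covariate they were 144, 227 and 379 for testosterone 0.1 mg, 0.2 mg for 7 days and the mean, 122 for the doses, 44 for 11-ketotestosterone against 7 days, and 711 for the F test. For all of these the cause was not tested, though the block also takes untreated fish 8 to 14 out of its fit, which lowers precision by construction. Testing 591 genes in place of 9024 clones gave, by construction, fewer: 44, 91, 73 and 25 against untreated, 85 for the mean, 51 for the doses, 22 for the durations, 30 and 24 for the androgens, and 114 for the F test. A fold of at least 1.5 in addition to the threshold, a stricter rule, left 84, 385, 290 and 93 against untreated, 176 for the mean and 210 for the doses. Leaving out each fish in turn gave 184 to 345 clones for testosterone 0.1 mg, 415 to 892 for 0.2 mg for 7 days, 461 to 706 for 14 days, 124 to 181 for 11-ketotestosterone, 723 to 908 for the mean and 835 to 1317 for the F test. It gave 121 to 441 for the doses, 105 to 303 for the durations, and 54 to 275 and 90 to 151 for the androgens. Among 10859 such values for named genes, which include differences without a call, 367 lost and 64 gained a call. Of 64 list tests 15 passed, against 4 with an estimated correlation, 15 with fry (3 lost, 3 gained), 15 with the brightest clone per gene, 11 without the 4 arrays (0 with an estimated correlation, lowest adjusted p = 0.0921) and 27 of 96 with list members through the array's own spellings, where 12 lists had 5 genes or more, and 0 of those 96 with an estimated correlation (lowest adjusted p = 0.0539). The number of fish per group, 4 to 14, limited precision, and signal over background was not analysed here.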

Other observations

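The tests among untreated fish in this part were set before their results were seen, and the tests of the ribosomal list with added spellings were chosen after seeing the data.

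Of 4 spermatogonial genes rtnanos3 rose with testosterone 0.2 mg for 7 days at 0.61 ± 0.13 (adjusted p = 0.00223) (1 adjusted over the list alone), above the untreated mean in 4 of 4 fish. These fish lay at 5.99 to 6.33, within the untreated range of 5.29 to 6.38. Of 2 meiosis genes sycp3, of the synaptonemal complex, rose in that group at 0.58 ± 0.19 (adjusted p = 0.0432), and 1 fell (1 and 1 adjusted over the list alone). The call of sycp3 was lost without any 1 of 6 fish (adjusted p = 0.0522 to 0.269). The other meiosis gene, calr3a, fell with 14 days of testosterone at -0.71 ± 0.20 (adjusted p = 0.0166), and was lost without fish 1, 4 or 5 of that group (adjusted p = 0.0691, 0.0575 and 0.0732). In limma 0 of 2 spermiogenesis genes and 0 of 1 oocyte gene changed in 9 comparisons. At an unadjusted p under 0.05, 1 spermiogenesis gene fell with testosterone 0.2 mg for 7 days and 1 was higher with 11-ketotestosterone (duration uncertain) than in that group, the latter also adjusted over the list alone.

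Of 2 leukocyte genes lect2 rose with testosterone 0.2 mg at 7 days, 1.04 ± 0.21 (adjusted p = 0.000681), and at 14 days, 0.83 ± 0.19 (adjusted p = 0.00333) (1 adjusted over the list alone each time, and 1 fell at 7 days). The 1 cholesterol gene measured rose in both these groups (1 adjusted over the list alone in each). In limma 0 of 4 chaperone genes changed in 9 comparisons, and 1 was higher with 11-ketotestosterone than with 7 days of testosterone adjusted over the list alone. At an unadjusted p under 0.05, 1 chaperone gene changed in each of 4 comparisons. The 4 genes leave out hsp47, which rose with 14 days of testosterone and joined this list only through the array's own spellings. Of 5 growth factor genes igfbp3 rose at 0.42 ± 0.13 (adjusted p = 0.0392) and igfbp7 fell at -0.79 ± 0.18 (adjusted p = 0.00383) with testosterone 0.2 mg for 7 days (1 and 1 adjusted over the list alone; camera adjusted p = 0.972, with a median of 0.11 and a mean of -0.02). The call of igfbp3 was lost without any 1 of 9 fish (adjusted p = 0.0503 to 0.225). Of 6 ribosomal protein genes 1 fell with testosterone 0.1 mg (1 adjusted over the list alone). The camera test did not pass for the liver and plasma, ribosomal, oxidative phosphorylation, receptor and globulin, and growth factor lists in any of 8 comparisons, with adjusted p = 0.119 as the lowest, for the ribosomal list at 14 days, where fry passed (adjusted p = 0.0351). With members added through the array's own spellings the ribosomal list held 20 genes and lay lower by camera with testosterone 0.1 mg (adjusted p = 0.00456), testosterone for 14 days (0.000688), 11-ketotestosterone of uncertain duration (0.00286) and in the mean of the testosterone groups (0.000677). With an estimated correlation these were adjusted p = 0.273, 0.169, 0.254 and 0.169.

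The 14 untreated fish may carry the androgen response to different degrees. If so, fish with more signal in the 491 clones that rose with testosterone would have less in the 354 that fell. The correlation of the 2 means was -0.402 (permutation p = 0.152, adjusted p = 0.246; rank correlation -0.442, p = 0.115). Of 2000 random sets of clones matched on signal, a share of 0.042 had a correlation as low, with a median of 0.31. Without the 2 fish farthest from the others it was -0.084, so the data leave this open.

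By the same reasoning untreated fish with more il13ra2b could have less cyp17a1. The correlation over the 14 fish was -0.335 (permutation p = 0.246, adjusted p = 0.246; rank correlation -0.235, p = 0.418), and -0.335 without the 2 fish farthest from the others. This relation did not pass its test.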
